A study of Homo sapiens with 4 samples.

How the data were processed

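RNA was measured in Raji cells, an established human B cell line from a Burkitt lymphoma that carries Epstein-Barr virus. The cells received a vector for an HA-tagged, α-amanitin-resistant RPB1, the large subunit of RNA polymerase II, either wild-type (WT) or with the R1810A substitution, which puts alanine in place of an arginine of the C-terminal domain that can be methylated. α-Amanitin blocks the endogenous polymerase, so the resistant subunit takes over transcription during the 10 days of selection. Per the labels' protocols, the lines were polyclonal, ribosomal RNA was removed from total RNA with a capture kit, and libraries were read on an Illumina GAII. There were 4 libraries, 2 of each kind. Nothing in the labels says whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

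The deposited files hold, for each library, the read count, the RPKM, the gene length and a total read number for each of 51714 Ensembl gene identifiers. Reads were aligned with Bowtie to hg19, per the submitters' processing notes, with no version named. The counting program, the annotation release, the use of strand and the treatment of reads that match several places are not given in the sources used here. The counts are the authors' raw read counts per gene, per the file headers, and were not normalised. The deposited RPKM values equalled the count scaled by the deposited gene length and the deposited total reads in every row, within a relative tolerance of 0.0001, so they carried no further information and were not tested. What the deposited total reads number counts (sequenced, mapped or uniquely mapped reads) is not stated. Summed gene counts were 2326036 and 2991959 in the WT libraries and 2116444 and 2081636 in the R1810A libraries, against total reads of 4097635, 5405229, 4017398 and 4128532. At this depth a gene with few reads has a wide counting error, and intervals given for shares of counts are exact Clopper-Pearson intervals at 95% that cover counting error only.

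Gene symbols came from a table of current names and from a gene annotation of another genome build. That annotation also gave gene types, the chromosome of mitochondrial genes, and the nesting of small RNA genes in host genes. Nesting and the overlap of host exons with small RNAs rest on its coordinates, not on those of the build used for counting. Of the identifiers, 40926 received a symbol. The 10788 without one held 7.49% of the counts, kept their identifier and were tested like the rest. The U1 snRNA family, with near-identical copies, had few reads (22 and 49 in WT, 104 and 51 in R1810A). Some mitochondrial genes also had few, such as MT-ND2 with a mean count of 91, while MT-ND3 had 1178.2. Reads shared between copies may therefore have been dropped or split by the counting. Values of single members of the snRNA, snoRNA, histone and mitochondrial families are uncertain to that extent.

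The comparison was R1810A against WT with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, glmQLFit and glmQLFTest with group as the only term, and Benjamini-Hochberg adjustment at 0.05. The filter kept 10674 genes. Levels are CPM, counts relative to library size, with TMM scaling, as mean ± SD of 2 libraries, and folds are R1810A over WT from the edgeR fit. The SE printed with a log2 fold change is its absolute value divided by the square root of the F statistic of the edgeR test. It is not a separately estimated error, and for genes of few reads, such as RNU5F-1, it can be smaller than the counting error. Fixed gene lists, 30 in number, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 26 lists with at least 3 tested members. Members past the threshold were counted over all genes and adjusted over the list alone. The lists of snRNA, C/D and H/ACA snoRNA and small Cajal body RNA were chosen because the published study of these same samples is known to concern those classes, so they are not independent evidence of direction. Enrichment among called genes was tested with a two-sided Fisher exact test against all genes tested, and shares of counts with a two-sided exact permutation test, for which 2 against 2 libraries allow no p below 0.333.

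The lists, the comparison, most alternatives and the rule for naming genes were set before the data were examined. The rule takes the 12 largest fold changes per direction among genes past the threshold with a mean count of at least 20 and no overlap between groups, up to 4 passing members of each list by p (where none pass, the 2 with the smallest p), and POLR2A, CARM1 and TDRD3. Genes named outside it are said to be so, and some genes that the rule takes are not reported here. The symbol pattern fixed for the snRNA list missed RNU5A, RNU5E and RNU5F symbols and took in U2AF1 and U2AF2, which code for proteins and were removed, as was MTTP from the mitochondrial list. A list of all tested genes annotated as snRNA was therefore added as an alternative. Alternatives were other scalings (DESeq2 size factors, upper quartile, summed counts alone, scaling without small RNA, mitochondrial and histone genes), no filter, a mean count of at least 20, DESeq2 1.42.0, limma-voom, robust edgeR, the replicate number as a block, each library left out, a fold threshold of 1.5, camera with an estimated correlation, and fry. Scaling by the deposited total reads, summed small RNA families and the wider snRNA list were added after seeing the data.

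The procedure was checked on simulated counts for R1810A against WT over 10507 genes. It recovered 36.4% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 98.5% of those changed 4-fold, and 4.93% of its 142 calls were false. A simulated list raised by 1 on the log2 scale had a median of 0.93, and 0 of the other lists were called. The simulated genes were drawn independently of each other. The check therefore cannot show how often lists are called wrongly when their members are correlated. Each gene was also drawn at the dispersion of the trend over all genes. The rates of recovery and of false calls therefore do not cover genes that vary more between libraries of a group than that trend. Figures were drawn with matplotlib 3.10.9, and the tests of the closing section used Python 3.11.15 with scipy 1.17.1.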

Results

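Total RNA depleted of ribosomal RNA was sequenced from Raji B cells whose RNA polymerase II carried either a wild-type large subunit (WT, 2 libraries) or the R1810A subunit (2 libraries), to learn whether loss of this methylation site changes gene expression. Summed gene counts ranged from 2081636 to 2991959 per library, with reads at 16414 to 17824 genes in each.

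POLR2A (ENSG00000181222), which codes for the replaced subunit, was measured at 865 ± 15.1 CPM in WT and 998 ± 64.4 CPM in R1810A (SD, n = 2), a log2 fold change of 0.21 (SE 0.11, adjusted p = 0.655). Both lines make recombinant RPB1 and the counts do not separate the vector from the endogenous gene, so this level does not check the labels. CARM1, the arginine methyltransferase known to act on this residue, stood at 328 ± 40.6 CPM in WT and 278 ± 14.99 CPM in R1810A (adjusted p = 0.647). TDRD3, a Tudor domain protein that binds methylated arginine, stood at 19.2 ± 5.40 and 21.9 ± 5.14 CPM (adjusted p = 0.904).

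Of 83 tested genes in the lists of snRNA, snoRNA and small Cajal body RNA, 24 were higher in R1810A cells, and few other genes passed the threshold. The lists of these classes passed at the preset correlation of camera, and no list passed with an estimated one. The U5 snRNA gene RNU5E-1 rose from 38.8 ± 0.275 to 301 ± 160.3 CPM (SD, n = 2), the U2 gene RNU2-2P from 16.7 ± 1.32 to 114 ± 76.2 CPM, and the H/ACA snoRNA SNORA33 from 7.54 ± 1.72 to 48.3 ± 11.8 CPM. CXCR4, a chemokine receptor of B cells, fell from 461 ± 42.9 to 288 ± 8.86 CPM. Of 10674 genes tested with edgeR, 37 were higher and 1 was lower in R1810A at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 527 and 327. DESeq2 called 39 higher and 2 lower, and limma-voom 24 and 1.

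Of the 37 higher genes, 24 belonged to the lists of snRNA, C/D snoRNA, H/ACA snoRNA and small Cajal body RNA. These lists made up 64.9% of the higher genes and 0.778% of the genes tested (odds ratio 327, Fisher exact p = 2.03e-43). The classes were chosen because the published study of these same samples concerns them, so the Fisher test is not independent evidence. That test treats genes as independent, although the estimated correlation within these lists reached 0.839, and the odds ratio was 54.7 without WT replicate 1 and 624 without R1810A replicate 2. A further 7 were short genes of 65 to 203 bases without a symbol, among them ENSG00000206653 (log2 fold change 3.57, SE 0.41). The other 6 were the U5 genes RNU5E-1 and RNU5F-1, the U5 copy RNU5A-8P (2 and 2 reads in WT, 49 and 21 in R1810A), the signal recognition particle RNA copy RN7SL160P, the snoRNA host gene GAS5 and GMFB, a glia maturation factor gene. RNU5A-8P and GMFB are outside the naming rule and were named after their values were seen. In all 37, both R1810A libraries lay above both WT libraries. Leaving out a library leaves 1 in its group, so the spread then comes from the other group alone. Both fits without a WT library take it from the same R1810A pair, so it does not account for the difference between those fits. Without WT replicate 2, with spread from the R1810A pair, 2 genes were higher and 0 lower. Of the 21 named genes past the threshold 20 then lost the call, while none changed direction and RNU5E-1 kept a log2 fold change of 2.96. Without WT replicate 1 the counts were 113 and 40.

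**Figure D1:**
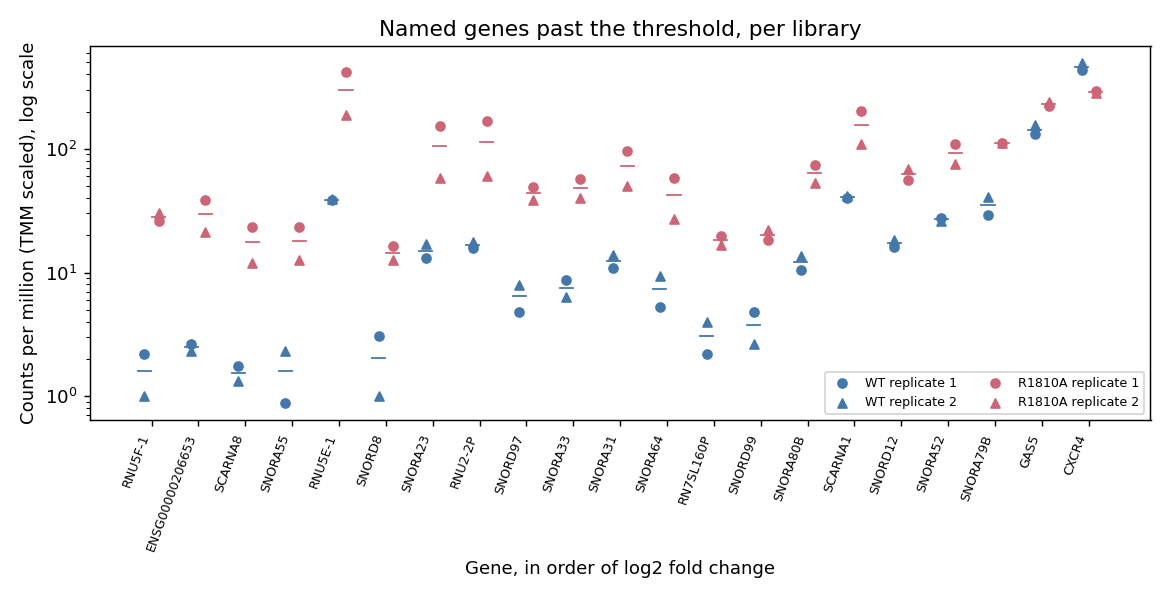
CPM with TMM scaling (log axis) of the named genes past the threshold in each library, with circles for replicate 1, triangles for replicate 2 and a line at the mean of each group. Genes run from the largest log2 fold change (RNU5F-1, 4.16) to CXCR4 (-0.68), the only one lower in R1810A, and in several snRNA and snoRNA genes R1810A replicate 1 lies well above replicate 2.

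Spliceosomal snRNAs recognise splice sites and catalyse splicing. The symbol pattern of the list of spliceosomal and U7 snRNA also admits pseudogene copies, so reads at a member need not come from a working snRNA. The list had positive fold changes in all 6 tested members, with a median log2 fold change of 2.10 (camera adjusted p = 4.31e-06, p = 0.155 and adjusted p = 0.708 with an estimated correlation). RNU2-2P rose (log2 fold change 2.76, SE 0.41, adjusted p = 0.013) and the other 5 did not pass over all genes, while 5 were higher adjusted over the list alone. RNU2-2P lost the call with limma-voom (adjusted p = 0.081), robust edgeR (0.559) and without WT replicate 2 (0.260), and its log2 fold change was 1.85 without R1810A replicate 1. The U5 genes stood outside the symbol pattern of this list. RNU5E-1 (ENSG00000199347) had 88 and 117 reads in WT and 865 and 391 in R1810A, a log2 fold change of 2.96 (SE 0.31, adjusted p = 0.0016) that was 2.27 without R1810A replicate 1. It lost the call with robust edgeR (adjusted p = 0.412) and without WT replicate 2 (0.157). RNU5F-1 (ENSG00000199377) had 5 and 3 reads against 54 and 63, a log2 fold change of 4.16 (SE 0.38). All 10 tested genes annotated as snRNA were added as a list after the data were seen. Of these 4 were higher, 9 were higher adjusted over the list alone and the median was 2.69 (p = 0.085 with an estimated correlation). The median of the 6 members was 0.92 without R1810A replicate 1. Because the published study found these classes on the same samples, the counts adjusted over the list alone are not independent evidence of direction, here and for the snoRNA classes.

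Box H/ACA snoRNAs, which guide pseudouridylation of ribosomal RNA, were positive in all 40 tested members, and 16 passed the threshold. SNORA33 (2.69, SE 0.28), SNORA80B (2.37, SE 0.24), SNORA52 (1.79, SE 0.20) and SNORA79B (1.66, SE 0.17) had the smallest p among them, and SNORA55 (3.37, SE 0.50) the largest log2 fold change. SNORA55 had 2 and 7 reads in WT and 49 and 26 in R1810A, with a log2 fold change of 2.85 without R1810A replicate 1 and 4.27 without WT replicate 2, where it lost the call (adjusted p = 0.157). SNORA23, SNORA31 and SNORA64 also rose, by 6.90-fold, 5.78-fold and 5.66-fold. SNORA23 and SNORA64 lost the call with limma-voom (adjusted p = 0.074 and 0.090), robust edgeR (0.517 and 0.063) and without WT replicate 2. Without R1810A replicate 1 the log2 fold changes of SNORA23, SNORA31 and SNORA64 were 1.93, 2.00 and 1.84. The list had a median log2 fold change of 1.82 (camera adjusted p = 1.00e-38), and 37 members were higher adjusted over the list alone. The call did not hold with an estimated correlation (p = 0.059).

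Box C/D snoRNAs, which guide ribose methylation of ribosomal RNA, were positive in 24 of 25 tested members. SNORD97 (2.72, SE 0.28), SNORD12 (1.84, SE 0.19), SNORD99 (2.46, SE 0.35) and SNORD8 (2.88, SE 0.47) were among the 5 that rose, and 22 were higher adjusted over the list alone. Reads at SNORD12 numbered 37 and 55 in WT and 117 and 142 in R1810A, whereas SNORD8 had 7 and 3 against 34 and 26. SNORD8 lost the call with limma-voom (adjusted p = 0.069), without WT replicate 2 (0.239) and without R1810A replicate 1 (0.053), and its log2 fold change ran from 2.21 to 3.78 with a library left out. The median log2 fold change was 1.72 (camera adjusted p = 1.10e-29). With an estimated correlation the p was 0.0060, which became 0.155 after adjustment over the lists, and fry kept this list (adjusted p = 0.021) and none of the others.

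Small Cajal body RNAs, which guide modification of snRNAs, were positive in 11 of 12 members with a median log2 fold change of 0.93 (camera adjusted p = 6.74e-07, p = 0.196 with an estimated correlation). SCARNA8 (3.51, SE 0.50) and SCARNA1 (1.94, SE 0.25) rose, and 8 were higher adjusted over the list alone. Both lost the call without WT replicate 2 (adjusted p = 0.228 and 0.191), and SCARNA1 also with robust edgeR (0.086). The median without R1810A replicate 1 was 0.37. All 4 medians stayed positive under every scaling tried. Scaling by the deposited total reads moved the median of all genes by -0.12 on the log2 scale, and the medians of the snRNA, C/D, H/ACA and small Cajal body lists were then 1.98, 1.60, 1.70 and 0.81.

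Shares of all counts do not depend on how reads are divided among near-identical copies within a class. Any reads dropped because they match several copies would still be missing from the shares. The 4 classes made up 0.259% (interval 0.253 to 0.266%) and 0.284% (0.278 to 0.290%) in WT. They made up 0.748% (0.737 to 0.760%) and 0.468% (0.459 to 0.477%) in R1810A. The group means of 0.271 ± 0.0171% and 0.608 ± 0.198% (SD, n = 2) differed 2.24-fold, with no overlap between groups (exact permutation p = 0.333, the smallest possible). The difference of 0.337 percentage points was 0.197 without R1810A replicate 1. H/ACA snoRNAs made up 0.121% of counts on average in WT and 0.322% in R1810A, and C/D snoRNAs 0.0546% and 0.133%, neither testable below that p. Small Cajal body RNAs stood at 0.0886 ± 0.0168% in WT and 0.128 ± 0.0352% in R1810A, a difference little larger than the SD in R1810A.

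Summed into families after the data were seen, U5 (RNU5) was 8.66-fold higher in R1810A (adjusted p = 0.0011), U2 (RNU2) 5.35-fold (adjusted p = 0.033), SNORA 2.67-fold (adjusted p = 0.022) and SNORD 2.44-fold (adjusted p = 0.012). The U1 family (RNU1 and RNVU1, 2.80-fold), the U4 family (RNU4, 2.72-fold), U6 (RNU6, 2.23-fold), the 7SL copies (RN7SL, 2.22-fold) and the 7SK copies (RN7SK, 2.04-fold) did not pass, with adjusted p between 0.070 and 0.272, nor did SCARNA (1.45-fold, adjusted p = 0.501). R1810A replicate 1 lay above replicate 2 in each of these families: RNU5 stood at 541 and 248 CPM in R1810A against 47.8 and 43.6 in WT, and RNU2 at 195 and 74.1 against 24.1 and 25.97. The gene annotated under the symbol 7SK itself, named here after its value was seen, had 80 and 107 reads in WT and 79 and 80 in R1810A (log2 fold change 0.11, SE 0.17).

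**Figure D2:**
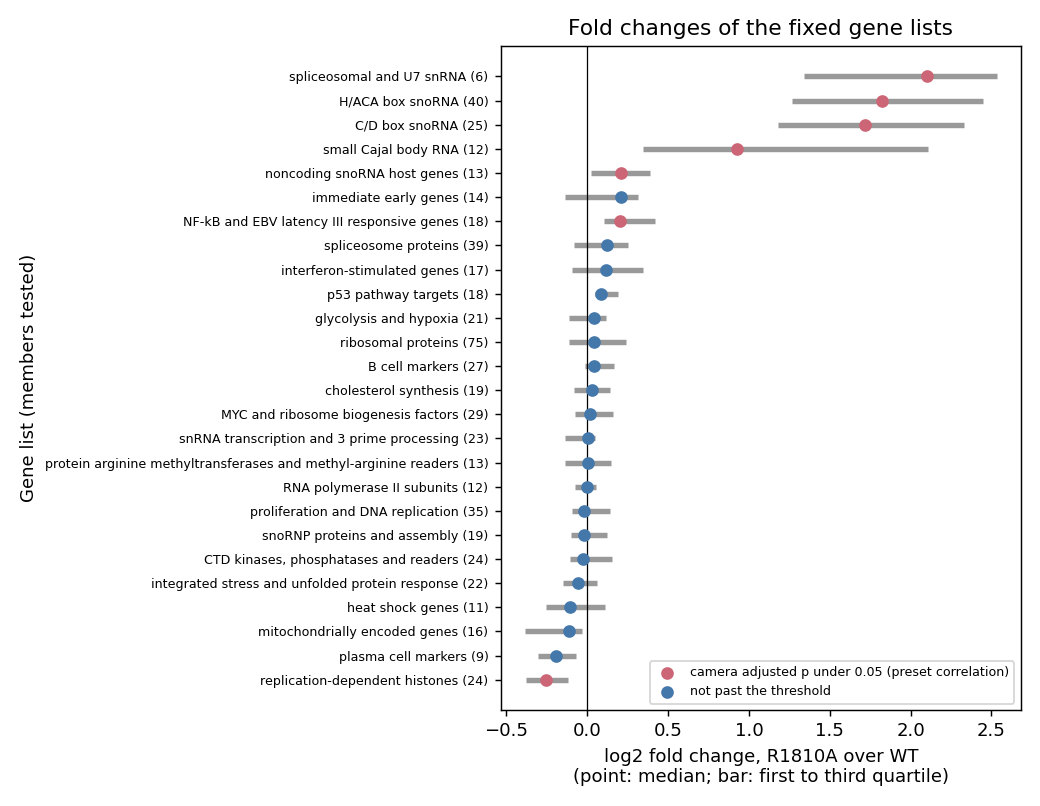
Median log2 fold change (R1810A over WT, point) and interquartile range (bar) of the tested members of each fixed list, with the number of members tested in brackets and colour for lists past the camera threshold at the preset correlation. The 4 small RNA classes lie between 0.93 and 2.10, and the medians of the other lists lie between -0.26 and 0.21, some of them on the other side of 0 under other scalings.

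Among noncoding host genes of snoRNAs, GAS5 (ENSG00000234741), whose introns hold several C/D snoRNAs, rose from 143 ± 16.7 to 231 ± 12.4 CPM (log2 fold change 0.68, SE 0.12, adjusted p = 0.046), and lost the call under 6 of 15 alternatives. It was the only one of 13 members to pass, 2 were higher adjusted over the list alone, and 10 fold changes were positive. The median was 0.21 (camera adjusted p = 0.0086, p = 0.082 with an estimated correlation). As a list the hosts lost the call without WT replicate 1 (median 0.17), R1810A replicate 1 (0.19) or R1810A replicate 2 (0.23). Proteins of the snoRNPs and their assembly had a median of -0.02 in 19 members, with RUVBL1 (-0.31, SE 0.11) and COIL (-0.82, SE 0.39) of smallest p. Factors of snRNA transcription and 3′ processing, among them the Integrator and SNAPc subunits, had a median of 0.00 in 23 members, with SNAPC4 at 0.37 (SE 0.16) and SNAPC1 at -0.57 (SE 0.27). No member of either list passed with edgeR, DESeq2 or limma-voom. At an unadjusted p under 0.05 there were 1 lower snoRNP protein gene and 1 higher snRNA factor gene, and the camera adjusted p were 0.729 and 0.665.

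Replication-dependent histone genes lay lower in R1810A as a list, with 20 of 24 log2 fold changes below 0 and a median of -0.26 (camera adjusted p = 0.00016, p = 0.121 with an estimated correlation). H2AC11 stood at 284 ± 18.0 CPM in WT and 189 ± 9.94 CPM in R1810A (log2 fold change -0.58, SE 0.11, adjusted p = 0.061), and H3C4 at 501 ± 28.0 and 356 ± 10.3 CPM (-0.49, SE 0.11, adjusted p = 0.102). The list lost its call without R1810A replicate 1 (median -0.20). No histone gene passed over all genes with edgeR as set, DESeq2 or limma-voom. H2AC11 passed with no filter (adjusted p = 0.011), robust edgeR (0.046), the replicate block (0.025), the deposited total reads (0.014) and without WT replicate 1 (0.016), and H3C4 with no filter (0.022), total reads (0.031) and without WT replicate 1 (0.021). In the edgeR test 9 were lower and 1 higher at an unadjusted p under 0.05, and 6 were lower adjusted over the list alone. Proliferation and DNA replication genes had a median of -0.02 over 35 members (camera adjusted p = 0.942), with MKI67 at 0.45 (SE 0.13) and PLK1 at -0.25 (SE 0.13). No member passed with edgeR, DESeq2 or limma-voom, and 1 was higher at an unadjusted p under 0.05. CXCR4 (ENSG00000121966) had 983 and 1476 reads in WT and 613 and 585 in R1810A (log2 fold change -0.68, SE 0.11, adjusted p = 0.027) and lost the call when any library except WT replicate 1 was left out.

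Genes of the polymerase and its regulation showed no called member with edgeR, DESeq2 or limma-voom. The 12 subunits of RNA polymerase II had a median log2 fold change of 0.00 (camera adjusted p = 0.934), with POLR2C at -0.17 (SE 0.14) and 0 members at an unadjusted p under 0.05. Kinases, phosphatases and readers of the C-terminal domain had a median of -0.02 in 24 members (adjusted p = 0.675), with the elongation factor SUPT6H at 0.52 (SE 0.15) and 2 higher members at an unadjusted p under 0.05. Protein arginine methyltransferases and readers had a median of 0.00 in 13 members (adjusted p = 0.942), with PRMT6 at 0.33 (SE 0.13) and WDR77 at -0.41 (SE 0.17), the 2 under that limit. Spliceosome proteins had a median of 0.13 in 39 members (adjusted p = 0.281). SF3B2 (0.69, SE 0.15, adjusted p = 0.116) and LSM3 (-0.67, SE 0.16, adjusted p = 0.186) missed the threshold, which LSM3 passed without WT replicate 1. There were 1 higher and 2 lower members adjusted over the list alone, and 6 higher and 2 lower had an unadjusted p under 0.05. Median, mean and direction of the test differed in sign for the lists of RNA polymerase II subunits, snRNA transcription, C-terminal domain regulators, arginine methyltransferases, proliferation and glycolysis, all with medians near 0.

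Ribosomal proteins had a median of 0.04 in 75 members (adjusted p = 0.290), which was -0.08 with the deposited total reads. RPL13A, a host of snoRNAs, stood at 0.52 (SE 0.11, adjusted p = 0.116), and 3 members were higher adjusted over the list alone. MYC and ribosome biogenesis factors had a median of 0.02 in 29 members (adjusted p = 0.665), -0.11 with total reads, with NCL at 0.54 (SE 0.15) and WDR3 at 0.25 (SE 0.14). Mitochondrially encoded genes had a median of -0.11 in 16 members (adjusted p = 0.057), with MT-ND2 at -0.61 (SE 0.19) and MT-TL1 at -1.47 (SE 0.56). MT-TL1 had 20 and 19 reads in WT and 2 and 9 in R1810A, and its log2 fold change was -2.90 without R1810A replicate 2 and -0.78 without replicate 1. None of these genes passed with edgeR, DESeq2 or limma-voom. At an unadjusted p under 0.05 there were 8 higher and 2 lower ribosomal protein genes, 1 higher biogenesis factor and 3 lower mitochondrial genes.

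Lists of cell identity and signalling held no called gene with edgeR, DESeq2 or limma-voom. B cell markers had a median of 0.04 in 27 members (adjusted p = 0.354), with CD72 at 0.60 (SE 0.18) and FCER2 at 0.64 (SE 0.30). Plasma cell markers had a median of -0.19 in 9 members (adjusted p = 0.114), with XBP1 at -0.32 (SE 0.11) and CD27 at -0.31 (SE 0.10). NF-κB and latency III responsive genes passed as a list (median 0.20 in 18 members, adjusted p = 0.045, p = 0.567 with an estimated correlation), with NFKBIA at 0.51 (SE 0.20) and CD83 at 0.45 (SE 0.22). Its median was -0.14 without WT replicate 2 and 0.78 without WT replicate 1. Interferon-stimulated genes had a median of 0.12 in 17 members (adjusted p = 0.354), with IFIH1 at 0.42 (SE 0.22) and OAS1 at -0.25 (SE 0.16). That median was 0.71 without WT replicate 1 and -0.36 without WT replicate 2, so the 2 WT libraries lay on either side. Without WT replicate 1 CD72, FCER2, NFKBIA and CD83 passed, with FCER2 at 1.25. The unadjusted p was under 0.05 for 1 higher B cell marker, 3 lower plasma cell markers, 1 higher NF-κB gene and 0 interferon genes.

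Stress and metabolic lists did not pass either, with 0 called members by any of the 3 tools. Targets of p53 had a median of 0.08 in 18 members (adjusted p = 0.290, ZMAT3 0.43, TP53INP1 0.46), the integrated stress and unfolded protein response -0.05 in 22 (adjusted p = 0.675, ATF4 -0.45, PHGDH -0.41) and heat shock genes -0.11 in 11 (adjusted p = 0.508, HSP90AB1 -0.34, HSPA8 -0.21). Immediate early genes had a median of 0.21 in 14 members (adjusted p = 0.290, KLF6 0.39, JUNB 0.30), cholesterol synthesis 0.03 in 19 (adjusted p = 0.729, SC5D 0.18, STARD4 0.21) and glycolysis and hypoxia 0.04 in 21 (adjusted p = 0.942, PFKL 0.31, P4HA1 -0.37). The numbers at an unadjusted p under 0.05 were 2 higher p53 targets, 1 lower stress gene, 1 lower heat shock gene, 2 higher immediate early genes, 0 cholesterol genes, and 1 higher and 1 lower glycolysis gene. ZMAT3 and PHGDH passed without WT replicate 1.

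Markers of other cell types were sparse. T and NK cell markers totalled 34 to 41 reads per library, with LCK the 1 tested member (log2 fold change 0.31, SE 0.30), and epithelial and fibroblast markers 7 to 18 reads with 0 tested members. Myeloid and erythroid markers totalled 518 and 457 reads in WT and 579 and 388 in R1810A, mostly from CSF1R (0.30, SE 0.21), with ITGAM at 0.53 (SE 0.33, and 1.18 without WT replicate 1), neither past the threshold. The list of other small structured RNA had no tested member and 1 to 5 reads per library. Of its 17 fixed members, 7 were found by symbol and 3 of these had a read. Its 7SK entry was counted under another symbol, and why the other members were missing or empty was not tested. The list therefore does not show that these RNAs were absent.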

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

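The reads outside gene counts and the tests over other short genes and over RNA polymerase III families were chosen only after the values were seen. The bound for the other short genes was also changed after its values were seen: under the earlier bound, that all of them lie below the first quartile of the small RNA genes (1.13), 15 of 125 did not and the explanation stayed open. The tests of length and of scaling were set before.

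The share of the deposited total reads that is absent from the gene counts lies outside the measurement used in the comparison and was higher in the R1810A libraries. It was 43.2% and 44.6% in WT and 47.3% and 49.6% in R1810A, with means of 43.9 ± 1.00% and 48.45 ± 1.60% (SD, n = 2, exact permutation p = 0.333, the smallest possible). What the total counts is not stated, so these reads cannot be assigned to introns, ribosomal RNA or other sequence, and no explanation was tested.

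The higher level of snRNA and snoRNA genes in R1810A was seen over 83 genes with a median log2 fold change of 1.79, and medians of each R1810A library against each WT library ran from 1.28 to 1.90, against 0.29 between the WT libraries and 0.50 between the R1810A libraries. Scaling of the libraries is argued against, since the median was 1.67 with the deposited total reads, which moved all genes by -0.12. With scaling over other genes it was 1.792, but that test could hardly have come out otherwise. The 4 classes held on average only 0.271% of counts in WT and 0.608% in R1810A, so leaving them out barely changes the scaling. A rise shared by every short gene is argued against by the medians of the other genes of at most 400 bases. The 125 of them, 8 called higher, had a median of -0.03875 (SD 0.90) and the 47 that are not pseudogenes -0.00 (SD 1.17). Both lie below the median of the small RNA genes by more than their spread, a bound chosen after the values were seen. A rise in part of the other short genes stays open. The third quartile of the 47 was 1.311, above the first quartile of the small RNA genes (1.125). Better recovery of short RNAs in the R1810A libraries may still account for part of the higher small RNA level and cannot be told apart from the substitution. Across the 83 genes, which are not independent replicates, fold change went down with length without passing a test (Spearman rho -0.191, permutation p = 0.083, Pearson r -0.20, permutation p = 0.067, and -0.12 without the 2 genes farthest from the median length). A rise shared with products of RNA polymerase III cannot be told apart either. The summed copies of RN7SL, RN7SK and RNU6 had fitted folds of 2.22, 2.035 and 2.23, none past the threshold after adjustment. Each family lay higher in both R1810A libraries than in both WT libraries, with unadjusted edgeR p of 8.07e-05, 5.93e-05 and 0.0015. These values met the outcome written down for this explanation. These families held only 18 to 206 reads per library, and the counts do not show whether RNA polymerase III made those reads. The gene 7SK itself was at 1.08-fold. A bound of 1.2 on it, which was not part of the written outcome, kept the explanation open. The substitution remains open, untested apart from culture and library.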

How the results depend on the processing

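Scaling by total reads and the wider snRNA list were chosen after seeing the data. Genes higher in R1810A numbered 37, and 32 to 51 under 5 other scalings, a mean count of at least 20 (33), DESeq2 (39) and robust edgeR (40, of which 29 were shared). There were 78 without the filter, 24 with limma-voom, 24 over a fold of 1.5, and 2 to 113 with a library left out. Genes lower numbered 1, against 2 with total counts only, 7 without the filter, 2 with DESeq2, 4 with robust edgeR, 5 with total reads, 0 over a fold of 1.5 and 0 to 40 with a library left out. With the replicate number as a block there were 73 and 4, including all 37. Libraries of the same number did not deviate together (correlation -0.040), which gives no sign of pairing but does not exclude it. The list medians do not change with the list test: the snRNA (2.10, adjusted p = 0.708 and 0.469), H/ACA (1.82, 0.708 and 0.271) and small Cajal body RNA lists (0.93, 0.708 and 0.503) lost the call with an estimated correlation and with fry, and C/D (1.72, 0.155) with the former. The 4 classes otherwise kept direction and call under every scaling, filter and library left out, as did the enrichment where it could be computed (it was not with the 2 calls left without WT replicate 2). The share of counts, which had no call, kept its direction with each library left out. Without WT replicate 2 the NF-κB median reversed to -0.14 (range to 0.78 over left-out libraries) and the interferon median to -0.36 (range to 0.71), which passed as lower. Without WT replicate 1 the B cell (0.14), p53 (0.29), interferon (0.71, as higher) and mitochondrial (-0.29) lists passed, the last also without R1810A replicate 2 (-0.25) and with the block (-0.10). The NF-κB list lost the call with no filter (0.19), limma-voom (0.34) and without R1810A replicate 2 (0.17). Of 21 named genes past the threshold, 277 of 314 alternative values kept the call, 37 lost it and 0 changed sign. That tally leaves out the fold threshold of 1.5, under which 24 genes were higher and 0 lower. Another 41 list medians and 4 gene values changed sign with no call on either side. The cause of these changes was not tested, beyond fewer libraries or fewer genes tested. At this depth genes of few reads were measured poorly, and 1.5-fold changes were mostly missed in simulation.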

Other observations

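The tests on hosts and on length below were set down before their results were seen, and the values on library distance and unnamed genes were looked at afterwards.

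The most abundant feature of all libraries was ENSG00000199916, a gene of 264 bases without a symbol here, with 90188 and 119007 reads in WT and 89569 and 75027 in R1810A, or 3.60% to 4.23% of the counts per library. Among genes without a symbol, ENSG00000252678, of 333 bases, followed with 15864 and 27144 against 25803 and 15741 reads. Neither differed between the groups beyond the spread of libraries (log2 fold change -0.00, SE 0.16, and 0.32, SE 0.21). Among genes with a mean count of at least 100, the median absolute log2 ratio was 0.154 between the WT libraries and 0.113 between the R1810A libraries, and from 0.148 to 0.161 between libraries of different groups, a range that takes in the value of the WT pair.

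Histone genes kept their direction in each pair of libraries, with medians of the log2 ratio of R1810A over WT from -0.29 to -0.15, against 0.05 between the WT libraries and 0.11 between the R1810A libraries. Just short of the threshold, and named after their values were seen, were the DNA polymerase delta subunit gene POLD2 (log2 fold change -0.76, SE 0.14, adjusted p = 0.061, past it under 8 of 16 alternatives, DESeq2 among them) and the translation initiation factor gene EIF3A (0.66, SE 0.12, adjusted p = 0.061, past it under 5 of 16).

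A hypothesis was that small RNA reads counted within host exons could raise host genes. The 29 tested hosts with an exon over the small RNA had a median log2 fold change of 0.03 (bootstrap interval -0.05 to 0.12) and the 127 without one 0.04 (-0.03 to 0.07), a difference of -0.0043 (permutation p = 0.955), against -0.00 for 9184 other protein-coding genes. The hypothesis of miscounted reads is left open, since the hosts as a set were hardly shifted, and GAS5 was outside this set. Hosts of members with few reads could hardly be raised in this way, which limits what the set can show.

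Among 9328 protein-coding genes fold change tended up with gene length, by 0.039 per doubling (bootstrap interval 0.033 to 0.045), with a median of -0.05 for the 233 genes of up to 1000 bases and 0.07 for the 1163 genes of 8000 to 16000 bases. Low counts of short genes are argued against as the cause, because the slope was 0.0429 (0.037 to 0.049) among 5213 genes with a mean count of at least 100. A trend between single libraries is a candidate explanation: the slope of WT replicate 2 over replicate 1 was 0.05152 (0.042 to 0.061), as large as that between groups, and that of R1810A replicate 2 over replicate 1 was 0.0063. The trend therefore may reflect library differences within WT, and no biological explanation was tested.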
